A study of Mus musculus with 4 samples.

How the data were processed

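RNA was measured in 4 libraries from mouse neonatal cardiac fibroblasts at day 7 of treatment, 2 with a hairpin against Nr4a3 and 2 with a non-targeting hairpin, grouped by their titles. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into libraries with a stranded mRNA kit and sequenced as paired ends on an Illumina HiSeq X; the labels also give the molecule as polyA RNA, and the sources used here do not say whether poly(A) selection was applied. Per the submitters' processing notes, the build was mm10 and the tools were Trimmomatic 0.36, featureCounts, Subread 1.5.1 and SAMtools; the roles of these tools, the aligner and the strand setting of the counting are not given in the sources used here.

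The deposited table holds raw counts per gene for each library, per the file headers and the values, which are whole numbers. It lists 13192 genes, none with a mean count under 10.25 over the libraries, so genes below about that level were left out before deposit. The deposited FPKM values were computed by the authors from gene length and the sum of the counts listed in the table: dividing them out gave a whole-number gene length for 100% of nonzero values, within 0.01 bases. FPKM was used only to recover those lengths. The deposited log2 fold change, its standard error and the p-value are the authors' own comparison of shNr4a3 with shNT; the deposited p-value was recomputed from them as a normal test against an absolute log2 fold change of 0.5, with a largest difference of 6.7e-16. The deposited mean signal per gene, an average of counts divided by size factors, was not used here.

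Differences were tested on the counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, group as the only term), with TMM factors and the default filterByExpr filter, which removed 32 genes and left 13160. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and an adjusted p in the report is from this test unless another tool is named. The standard error of a log2 fold change was taken as its size divided by the square root of F. Normalised CPM uses the TMM factors. Gene lists, 31 in number with 962 members, were fixed before the data were examined; 848 members matched a listed gene, 49 of them through an older or newer symbol. The red blood cell list had no matched member, and the NR4A list has 3 members and was described gene by gene. The other 29 lists, each with at least 5 tested members, were tested two-sided with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry, which asks whether the genes of a list move on balance 1 way and compares them with no other genes. With an estimated correlation, camera relies on the few degrees of freedom left by 4 libraries, so a list can hardly pass it here.

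Named genes followed a rule fixed before the data were examined: the NR4A genes; among genes past the threshold with a mean log2 CPM of at least 1, both shNr4a3 libraries on the same side of both shNT libraries and an assigned symbol, the 12 largest changes in each direction; up to 4 members of each list with the smallest p; and a fixed set of genes on senescence, reprogramming and fibroblasts. The values of some genes that the rule names are not reported here. Genes outside the rule are marked in the text as named after their values were seen. Positions are from GENCODE M21 on GRCm38, in which 96.3% of the listed symbols were found.

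The common biological coefficient of variation was 6.6%. Replicates differed by more than sampling noise, with a chi-square per gene of 11.2 between the shNT libraries and 3.99 between the shNr4a3 libraries, so none was treated as a second copy of another; this does not show that they are separate cultures. Component 1 of log2 CPM held 80.9% of the variance, and Pearson r across genes was 0.990 and 0.991 within groups and 0.954 to 0.957 between them. The 20 most abundant genes took 12.9% and 12.3% of counts in shNT and 10.8% in each shNr4a3 library. Floors of 3 counts per library cover counting error only.

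The test was tried on simulated data: in 5 tables of 13112 genes made from these libraries, each with 200 genes changed, edgeR found 63.0% of genes changed by 0.5 on the log2 scale and 84.6% of those changed by 1, with 4.6% false calls and 0 of wrong sign. Camera found 5 of 5 raised lists and called 0 of 100 unchanged lists. Simulated genes varied independently of each other, and a far smaller share changed than the 55.5% called in the real data. These rates therefore do not show how the tests behave on the real counts, where genes of a list can move together. Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios and upper-quartile factors, library totals only, no filter and a stricter filter, the replicate number as a block, each library left out, the dominant and mitochondrial genes removed, and a minimum fold. A test against a log2 fold change of 0.5 and a correction for gene length were added after seeing the data. The length correction was run in a first version that also removed each library's mean deviation and so moved the centre of all fold changes; that version was replaced, after its counts had been seen, by one that removes the length trend alone, and only the second is reported. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.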

Results

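RNA-seq libraries were compared from mouse neonatal cardiac fibroblasts carrying a short hairpin RNA against Nr4a3 (shNr4a3) or a non-targeting hairpin (shNT). A short hairpin RNA is an RNA that a cell processes into a small interfering RNA, which lowers the transcript it matches. Each group had 2 libraries, collected at day 7 of treatment, and the labels give neonatal as the batch of all 4; the titles also carry the tag P3, which the labels do not explain. Read counts assigned to the 13192 listed genes came to 34068241 and 35111013 in the shNT libraries and to 34246969 and 34813598 in the shNr4a3 libraries. Fn1, which encodes fibronectin, was the most abundant gene in every library, with 1.86% to 2.17% of the counts. The labels do not say that replicates are separate cultures, so the p-values given here measure only the spread between these samples, which may be technical.

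The series asks by what molecular route loss of Nr4a3, an orphan nuclear receptor, favours the reprogramming of fibroblasts into cardiomyocyte-like cells, and its title names senescence as a barrier to that process. The single comparison of the design is shNr4a3 against shNT. Nr4a3 (GRCm38 chromosome 4, 48045153 to 48086447) had 60 and 29 counts in the shNT libraries and 4 and 8 in the shNr4a3 libraries. Its log2 fold change was -2.98 ± 0.67 (SE, n = 2 per group), a 7.91-fold lower level (adjusted p = 3.22e-04, edgeR). The level was low even in shNT, at 1.35 ± 0.70 normalised CPM (SD, n = 2; CPM is a gene's count scaled to a common library size), so the size of the fall is loosely determined: the log2 fold change ran from -2.33 without shNT replicate 1 (adjusted p = 0.0287) to -3.54 without shNr4a3 replicate 2 (edgeR). The related receptor Nr4a1 fell by 0.79 on the log2 scale (adjusted p = 3.65e-08, edgeR). Nr4a2 had a log2 fold change of 0.69 ± 0.34 that did not pass (adjusted p = 0.0873, edgeR); it passed without shNT replicate 2 (0.99, adjusted p = 0.0414) and with scaling by library totals only.

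**Figure D1:**
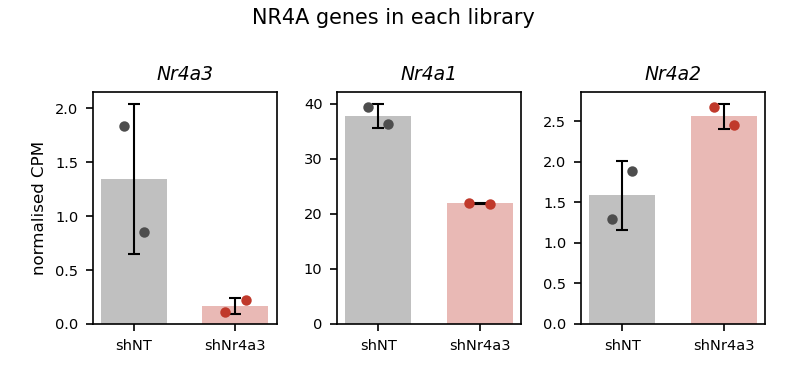
Normalised CPM (y axis) of Nr4a3, Nr4a1 and Nr4a2; points are the 2 libraries of each group, bars their mean and error bars the SD. On the log2 scale Nr4a3 fell by 2.98 (2.33 to 3.54 with 1 library left out) and Nr4a1 by 0.79; Nr4a2 did not pass the main test but did in 2 alternatives.

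Most tested genes differed between the groups, in about equal numbers each way, and large falls outnumbered large rises. Of 13160 genes tested, 3635 were higher and 3674 lower in shNr4a3 at an adjusted p under 0.05 (edgeR), which is 55.5% of them. At an absolute log2 fold change of at least 1, 446 genes were higher and 1070 lower; at 2 or more, 115 and 352. Scaling by library totals alone moved the median log2 fold change of all genes by 0.113, and the split then became 4702 higher and 2837 lower, 62.4% higher against 49.7% in the comparison as reported. In 77.2% of genes the 2 shNr4a3 libraries lay on 1 side of both shNT libraries, against 33.3% by chance.

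The genes with the largest rises by the fixed rule included Ttbk1, a tau kinase (log2 fold change 4.59 ± 0.17), Mtnr1a, a melatonin receptor (4.44 ± 0.21), Pappa2, a protease of IGF-binding proteins (4.70 ± 0.25), and Hgf, hepatocyte growth factor (3.28 ± 0.19). Stmn4 had 0 and 4 counts in shNT and 274 and 201 in shNr4a3. Fam131b, Sprr2k, Gp5 and Tmem169 rose too, as did the histone genes H4c18, H3c4 and H4c4. Sprr2k and the histone genes belong to families of near-identical copies, so reads can be split among them, and Pappa2 and Hgf share exon bases with a second gene on the same strand. The genes with the largest falls by the same rule included Msln, mesothelin, which fell by 4.33 (SE 0.08) on the log2 scale. Efemp1, an extracellular matrix glycoprotein, was 32-fold lower (log2 SE 0.13), and Itgb4, an integrin of epithelial anchoring junctions, fell by 4.44 (SE 0.17). Anxa8, Bst1, Pkhd1l1, Lrp2, Spp1, Nppb and the keratins Krt8 and Krt18 also fell. Krt14, with 203 and 183 counts in shNT and 0 in both shNr4a3 libraries, was at least 69.5-fold lower, against a floor of 3 counts per library. Each gene of this paragraph passed with an adjusted p of at most 3.36e-08 (edgeR). The smallest p of all tested genes belonged to Timp2, a metalloproteinase inhibitor, with 130414 and 131583 counts in shNT against 17698 and 17773 in shNr4a3.

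The genes tied to senescence moved in both directions. Among the cell cycle inhibitors and senescence markers, 9 of 19 tested members fell and 4 rose. Gdf15, a stress-induced cytokine, fell by 2.18 (SE 0.11), Hmga1, a chromatin protein, by 1.42 (SE 0.06), Plaur, the urokinase receptor, by 1.31 (SE 0.09), and Cdkn2b, which encodes p15, by 0.97 (SE 0.10). The 4 that rose, named after their values were seen, were Cdkn1c (1.84), Ptprj (0.98), Tnfrsf10b (0.49) and Cdkn1b (0.38). Cdkn1a, which encodes p21, had a log2 fold change of 0.09 ± 0.05 (adjusted p = 0.130, edgeR) and Cdkn2a, which encodes p16 and p19, of 0.15 ± 0.13 (adjusted p = 0.330, edgeR). When either shNT library was left out, Cdkn1a passed at 0.09 and 0.10, about its size in the main test. The spread then came from the shNr4a3 pair alone. Cdkn1a also passed at 0.20 with library totals only and at 0.13 with the gene length correction chosen after seeing the data. Cdkn2a passed at 0.42 without shNT replicate 2. Among the secretory phenotype genes, 21 of 41 fell and 16 rose: Timp2 was 7.98-fold lower (log2 SE 0.05), Mmp14 fell by 1.15 (SE 0.06) and Ereg by 1.21 (SE 0.06), while Il6, an inflammatory cytokine, rose by 1.35 (SE 0.10). Log2 fold changes in this list ran from -4.89 (Spp1) to 4.13, and Hgf (3.28) is a member that rose. Among p53 targets 13 of 30 rose, including Pmaip1 (1.44) and Plk2 (0.83), and 8 fell, including Perp (-1.94) besides Gdf15; the list did not pass camera (adjusted p = 0.41) but passed fry as higher (adjusted p = 0.047). The senescence marker list (adjusted p = 0.0015, camera) and the secretory list (adjusted p = 0.0019, camera) passed as lower, and neither did so with an estimated correlation (adjusted p = 0.23 with an estimated correlation for each). The senescence marker list also lost its call without the genes that stand in more than 1 list (adjusted p = 0.18, camera).

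**Figure D2:**
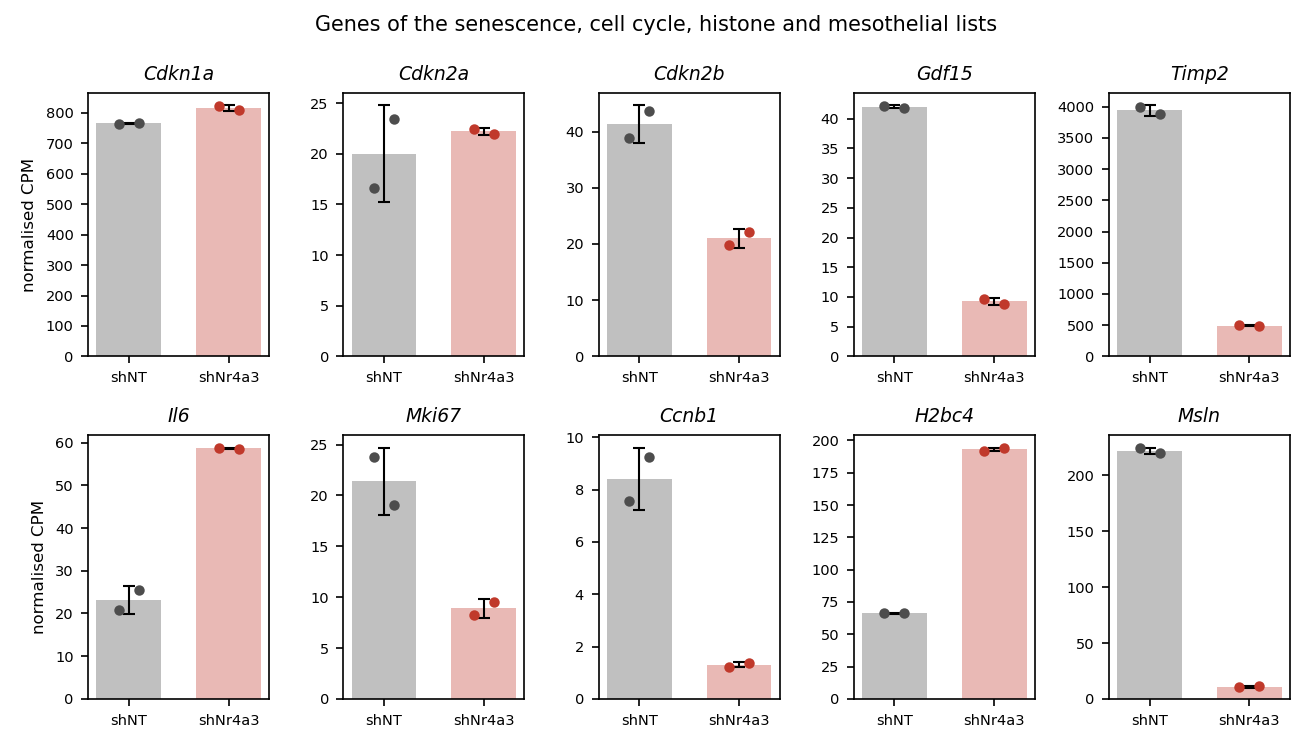
Normalised CPM (y axis) of 10 genes from the senescence, cell cycle, histone and mesothelial lists; points are the 2 libraries of each group, bars their mean and error bars the SD, each axis starting at 0. Cdkn1a and Cdkn2a did not pass the main test but did in some alternatives; Cdkn2b, Gdf15, Timp2, Mki67, Ccnb1 and Msln fell, and Il6 and H2bc4 rose.

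Mitotic genes fell while replication-dependent histone genes rose. Of 58 mitosis genes tested, 39 fell and 5 rose, with a median log2 fold change of -0.73. Kif11, a spindle motor, fell by 3.13 (SE 0.32), Ccnb1, cyclin B1, by 2.68 (SE 0.24), Anln, anillin, by 1.44 (SE 0.13) and Mki67, a proliferation marker, by 1.27 (SE 0.14). The 5 that rose, named after their values were seen, were Aspm (1.22), Hmgb2 (0.57), Ckap5 (0.39), Smc4 (0.39) and Gtse1 (0.34). Hmgb2 (0.46, adjusted p = 0.0557) and Gtse1 (0.26, adjusted p = 0.0783) did not pass without shNr4a3 replicate 1 (edgeR). Lmnb1, lamin B1, fell by 0.29 (SE 0.10; adjusted p = 0.0175, edgeR), a call lost with library totals only (-0.17) and without shNT replicate 1 (-0.21), shNr4a3 replicate 1 (-0.28) or shNr4a3 replicate 2 (-0.30). Of 47 DNA replication genes 17 fell, among them Rrm2 (-0.79), Mcm6 (-0.61) and Mcm10 (-1.56), and 4 rose, including Msh6 (0.95), Blm (0.73) and Pola1 (0.54), the last 2 named after their values were seen. Pola1 did not pass without shNT replicate 1 (0.29) or shNr4a3 replicate 2 (0.41). That list did not pass camera (adjusted p = 0.45) but passed fry as lower (adjusted p = 0.013). Of 21 histone genes 17 rose, with a list median of 2.52, including H2bc4 (1.54 ± 0.06), H2bc6 (2.90 ± 0.15), H1f4 (3.12 ± 0.18) and H1f2 (1.02 ± 0.06), and H2ax, a variant named after its value was seen, fell by 1.41. Mitosis (adjusted p = 0.0022) and histones (adjusted p = 1e-10) passed camera, with adjusted p = 0.23 with an estimated correlation for each.

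Genes of the heart muscle programme that were detected in these fibroblasts mostly fell or did not pass. The sample titles name a hairpin and no reprogramming factor, so these values do not measure reprogramming. Of 21 tested sarcomere genes 8 fell and 1, Ttn (1.32), named after its value was seen, rose. Myl4, an atrial myosin light chain, fell by 2.20 (SE 0.08), Myom1, myomesin, by 1.35 (SE 0.08), Tnnt2, cardiac troponin T, by 1.07 (SE 0.05) and Tpm1, tropomyosin, by 0.74 (SE 0.05). Myh6, with 15 and 32 counts in shNT and 8 and 24 in shNr4a3, had a log2 fold change of -0.66 ± 0.65 (adjusted p = 0.408, edgeR); Actc1 was not among the listed genes. Of 15 cardiac transcription factors and natriuretic peptides 8 fell, including Mef2a (-1.16), Tbx20 (-0.83), Srf (-0.48) and Nppb (-5.65; 120 and 172 counts against 2 and 4). Mef2c (0.46 ± 0.10) and Hand2 (0.31 ± 0.09, named after its value was seen) rose. Gata4 had a log2 fold change of -0.01 ± 0.06 (adjusted p = 0.919, edgeR) and Nppa of 0.15 ± 0.76 (adjusted p = 0.878, edgeR). Tbx5 fell by 1.07 (SE 0.38; adjusted p = 0.0184, edgeR), a call lost without shNT replicate 2 (-0.64, adjusted p = 0.276) or shNr4a3 replicate 1 (-0.67, adjusted p = 0.203). Of 21 ion channel and calcium handling genes 6 rose and 7 fell; Kcnj5, a potassium channel subunit, fell by 2.39 (SE 0.07) and Jph2, junctophilin, by 0.85 (SE 0.05), while Slc8a1, the sodium-calcium exchanger, rose by 0.74 (SE 0.10) and Gja1, connexin 43, by 0.56 (SE 0.10). The channel list did not pass camera (adjusted p = 0.38; median 0, mean -0.16) but passed fry as lower (adjusted p = 0.013). The sarcomere list (adjusted p = 0.0012, camera) and the factor list (adjusted p = 0.043, camera) passed as lower, with adjusted p = 0.23 and adjusted p = 0.33 with an estimated correlation. The factor list also lost its call with library totals only (adjusted p = 0.054), without shNr4a3 replicate 1 (adjusted p = 0.068) and without genes in more than 1 list (adjusted p = 0.059, camera).

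Fibroblast and matrix genes fell more often than they rose. Of 26 fibroblast identity genes 16 fell, including Tcf21, a transcription factor of cardiac fibroblasts (-1.91 ± 0.06), Mgp (-1.66 ± 0.08), Col1a1, the type I collagen alpha 1 chain (-1.15 ± 0.05), and Vim, vimentin (-0.97 ± 0.05). The 5 that rose, named after their values were seen, were Cd34 (1.11), Pdgfra (0.73), Lum (0.64), Tcf4 (0.37) and Dcn (0.16); Dcn did not pass without either shNr4a3 library (0.16 in both cases). Of 46 collagen and matrix genes 24 fell, including Col15a1 (-3.61), Prelp (-2.28) and Col16a1 (-1.31), and 16 rose. Of 35 myofibroblast and TGF-beta response genes 17 fell, including Pmepa1 (-0.88) and Cald1 (-0.71), and 9 rose, including Thbs2 (0.98) and Postn, periostin (0.59 ± 0.05). Acta2, smooth muscle actin, had a log2 fold change of 0.04 ± 0.05 (adjusted p = 0.496, edgeR), and passed at 0.06 without shNT replicate 1 and at 0.15 with library totals only. Adjusted over the list alone, 6 identity genes rose, 25 matrix genes fell, and 10 myofibroblast genes rose and 18 fell. Fibroblast identity (adjusted p = 1.5e-04) and matrix (adjusted p = 0.0099) passed camera as lower, with adjusted p = 0.23 and adjusted p = 0.54 with an estimated correlation; the myofibroblast list did not pass camera (adjusted p = 0.11), but passed as lower without shNT replicate 2 (adjusted p = 0.03, camera) and by fry (adjusted p = 0.023). The matrix list lost its call, and its median turned to 0.05, without the 20 most abundant and the mitochondrially encoded genes (adjusted p = 0.21, camera). That setting takes abundant members such as Col1a1 out of the list itself. The matrix list also lost its call without shNr4a3 replicate 1, where its median was -0.29.

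Markers of other heart cell types moved with the knockdown, most of them downward. Of 14 epicardial and mesothelial markers 13 fell, with a median log2 fold change of -2.90. Besides Msln and Efemp1, Upk1b, a uroplakin, fell by 3.32 (SE 0.09) and Krt7 by 3.26 (SE 0.11), whereas Upk3b (-0.76), named after its value was seen, fell less. Wt1 (-0.33, adjusted p = 0.0489, edgeR), also named after its value was seen, lost its call in 7 alternatives, with an adjusted p of up to 0.207. Aldh1a2 (0.29), also named after its value was seen, rose, and did not pass without shNr4a3 replicate 1 (0.19, adjusted p = 0.274, edgeR). Of 15 endothelial markers 13 fell, with a median of -1.92, including Emcn (-2.01 ± 0.09), Cdh5, VE-cadherin (-2.04 ± 0.09), Pecam1 (-1.86 ± 0.13) and Egfl7 (-2.60 ± 0.19). Flt1 (0.02, adjusted p = 0.840) and Vwf (-0.40, adjusted p = 0.604), named after their values were seen, did not pass (edgeR). Of 8 smooth muscle and pericyte markers 6 fell, including Cspg4 (-2.76), Mcam (-1.06), Myh11 (-0.83) and Lmod1 (-0.76). Rgs5 (1.65; 8 and 11 counts against 26 and 39), named after its value was seen, rose, and did not pass in DESeq2 or without shNT replicate 1 (1.47), shNT replicate 2 (1.87) or shNr4a3 replicate 2 (1.35). Of 5 glial markers 3 fell, including Ngfr (-2.22) and Cdh19 (-2.10), and S100b (1.04, adjusted p = 0.122, edgeR) did not pass; S100b passed without shNT replicate 1 (2.24, adjusted p = 0.0181). Only 6 of 23 macrophage and leukocyte markers could be tested: Lyz2 rose by 1.12, Cd14 (-1.58) and Cd68 (-1.09) fell, and Laptm5 (-1.58; 46 and 26 counts against 14 and 12) lost its call in DESeq2 (adjusted p = 0.0517) and without shNT replicate 1 or either shNr4a3 library. The mesothelial (adjusted p = 7.3e-29), endothelial (adjusted p = 1.4e-09) and smooth muscle (adjusted p = 5.2e-06) lists passed camera as lower, with adjusted p = 0.23, 0.23 and 0.34 with an estimated correlation. The glial (adjusted p = 0.41) and macrophage (adjusted p = 0.96) lists did not pass camera, though the glial list passed fry as lower (adjusted p = 0.011), and for the macrophage list camera pointed up while the median was -0.73.

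**Figure D3:**
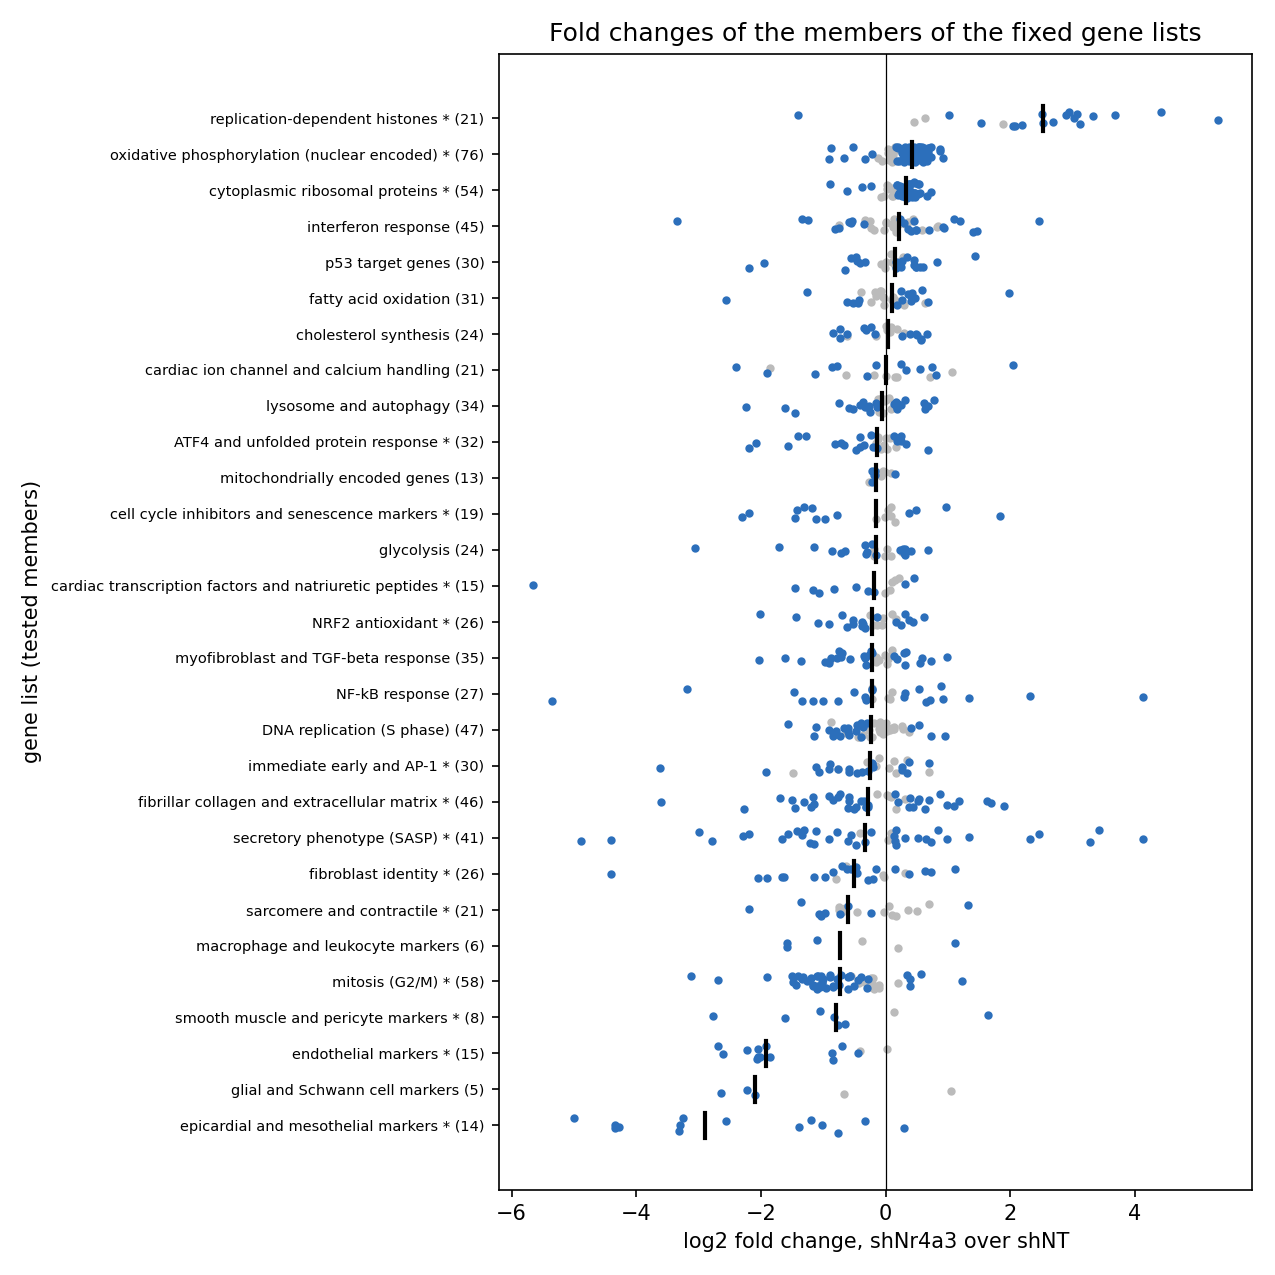
Log2 fold change, shNr4a3 over shNT, of the tested members of 29 gene lists; each point is a gene, blue where it passed an adjusted p under 0.05 (edgeR) and grey where not, black bars are list medians, and an asterisk marks lists that passed camera with the preset correlation. The lowest median is that of the epicardial and mesothelial markers at -2.90 and the highest that of the histone genes at 2.52.

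Among genes of the respiratory chain and the ribosome most members rose, by small amounts, and in 3 lists of stress and immediate early genes more members fell than rose; none of these lists passed camera with an estimated correlation, and the tests are given after the counts. Of 76 nuclear encoded oxidative phosphorylation genes 57 rose and 6 fell, with a median of 0.42; Uqcr10 rose by 0.88 (SE 0.09), while Sdha fell by 0.91 (SE 0.06), Cox8a by 0.87 (SE 0.08) and Atp5f1b by 0.52 (SE 0.05). Of 54 cytoplasmic ribosomal protein genes 38 rose, including Rpl37 (0.66) and Rpl32 (0.54), and 4 fell, which were Rpsa (-0.89), Rplp1 (-0.62), Rps6 (-0.38) and Rplp0 (-0.24), the last 2 named after their values were seen; Rplp0 did not pass without shNr4a3 replicate 1 (-0.23, adjusted p = 0.054, edgeR). Of 13 mitochondrially encoded genes 5 fell, including ND1 (-0.21), ND6 (-0.21), ND5 (-0.18) and CYTB (-0.17). With library totals only, each of these named genes lost its call, at -0.10, -0.10, -0.07 and -0.05 in that order. Each also lost it when either shNr4a3 library was left out, where the folds stayed between -0.15 and -0.23. COX1 (0.15), named after its value was seen, rose, and did not pass without shNr4a3 replicate 1 (0.11) or shNr4a3 replicate 2 (0.19). Of 24 glycolysis genes 11 fell, including Ldha, lactate dehydrogenase A (-1.71), Slc16a3 (-1.15), Hk2 (-0.86) and Pkm (-0.65), and 7 rose. Of 32 genes of the ATF4 and unfolded protein response 15 fell, including Trib3 (-2.19), Aldh1l2 (-2.08), Cebpb (-1.27) and Phgdh (-0.81), and 7 rose. Of 26 NRF2 antioxidant genes 13 fell, including Gstm1 (-1.43), Srxn1 (-0.91) and Txnrd1 (-0.69), and 6 rose, including Fth1 (0.61). Of 30 immediate early genes 15 fell, including Klf2 (-3.62), Klf4 (-1.92), Dusp1 (-1.06) and Maff (-0.89), and 5 rose, which were Dusp5 (0.69), Egr1 (0.38), Klf10 (0.34), Phlda1 (0.26) and Btg2 (0.26), named after their values were seen. Phlda1 did not pass in DESeq2 or without shNT replicate 2 (0.22), shNr4a3 replicate 1 (0.29) or shNr4a3 replicate 2 (0.24), nor Btg2 without shNr4a3 replicate 2 (0.23).

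Oxidative phosphorylation (adjusted p = 1.4e-06) and ribosomal proteins (adjusted p = 1.1e-04) passed camera as higher, each with adjusted p = 0.54 with an estimated correlation. Neither list passed fry (adjusted p = 0.076 and 0.10). Immediate early genes (adjusted p = 0.0044), the ATF4 response (adjusted p = 0.014) and the NRF2 list (adjusted p = 0.034) passed camera as lower, with adjusted p = 0.23, 0.26 and 0.31 with an estimated correlation. The NRF2 list lost its call with library totals only (adjusted p = 0.094, camera). Glycolysis (adjusted p = 0.12) and the mitochondrially encoded genes (adjusted p = 0.61) did not pass camera; glycolysis passed as lower without shNT replicate 2 (adjusted p = 0.037, camera) and by fry (adjusted p = 0.023). Adjusted over the list alone, 59 oxidative phosphorylation and 39 ribosomal genes rose, and 16 immediate early, 16 ATF4, 14 NRF2 and 16 DNA replication genes fell; counts were the same for the other 21 of 30 lists with tested members.

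Of the other lists, 15 of 45 interferon response genes rose and 9 fell, with Irgm1 (1.20) and Gbp2 (1.10) higher and Parp14 (-1.24) and Trim25 (-0.75) lower. Of 27 NF-kB response genes 12 fell, including Tnfaip2 (-1.46) and Ccl2 (-1.34), and 10 rose, including Il6. Log2 fold changes in that list ran from -5.35 to 4.13. Of 31 fatty acid oxidation genes 11 rose, including Fabp5 (1.98) and Decr1 (0.59), and 6 fell, including Ucp2 (-1.25). Of 24 cholesterol synthesis genes 7 rose, including Sc5d (0.67) and Stard4 (0.57), and 8 fell, including Cyp51 (-0.73) and Srebf2 (-0.62). Of 34 lysosome and autophagy genes 14 fell, including Ctsf (-1.62), Glb1, the beta-galactosidase (-1.45), Hexa (-0.59) and Ctsd (-0.53), and 11 rose. None of these 5 lists passed camera (adjusted p = 0.14, 0.68, 0.45, 0.73 and 0.35 in that order); by fry the interferon and fatty acid lists passed as higher (adjusted p = 0.047 for each) and the lysosome list as lower (adjusted p = 0.023). The cholesterol list had a median of 0.04 and a mean of -0.02, with camera pointing up.

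In total 16 of 29 lists passed camera with a preset correlation of 0.01, 3 as higher and 13 as lower; with an estimated correlation 0 passed in camera, with 2 at an unadjusted p under 0.05, and 23 passed by fry. Even the mesothelial list went from an unadjusted p of 2.5e-30 to 0.013 with an estimated correlation (camera). With so few libraries, failing that test does not show that inter-gene correlation undoes a list result. Of 168 named genes with a position in the annotation, 48 shared exon bases with another gene, 13 on the same strand and 38 on the opposite strand, and the strand setting of the counting is not given in the sources used here. The authors' deposited table marks 281 genes as up and 704 as down. These marks match an adjusted p under 0.05 by their test against 0.5 and an absolute log2 fold change above 1. All 281, and all 701 of the latter that were tested here, were called the same way by edgeR. The edgeR calls had no minimum fold and used the same counts, so this stricter set was likely to be called again. With a log2 fold change of at least 1, edgeR gave 446 higher and 1070 lower.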

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

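The test against a log2 fold change of 0.5 and the gene length correction were chosen after seeing the data. Counts of higher and lower genes stayed within 1.5 times under every scaling, filter, tool and left-out library run. They fell, by construction, to 446 higher and 1070 lower with an absolute log2 fold change of at least 1, and to 750 and 1351 when tested against 0.5. Leaving out 1 library at a time gave 2665 to 3848 higher and 2862 to 3758 lower genes and a Nr4a3 log2 fold change of -3.54 to -2.33; the lone library of a group is then assumed to vary like the other group. Nr4a3 passed in each of the 13 alternatives run for it; the filter at a CPM of 1 removed it, and the 2 minimum folds were applied to gene counts only. With the replicate number as a block, 3552 genes were higher and 3599 lower, Nr4a3 was at -2.90 and 16 lists passed; of the named genes only Wt1 lost its call. Deviations of same-numbered libraries correlated at -0.03, so no shift shared by number was seen. With 2 libraries per group a small shared effect cannot be excluded. The count of lists passing camera was 14 to 18 over the left-out libraries, and 0 with an estimated correlation. Correlations estimated from 2 libraries per group are imprecise, and reached 0.65 for the smooth muscle list. A correlation above the preset 0.01 does not account for every lost call. The histone (-0.04), senescence marker (-0.05), sarcomere (-0.05) and mitosis (0) lists were estimated below it and lost theirs too. The few degrees of freedom left by 4 libraries also limit that test. How far each matters was not tested. No named gene or list that passed changed sign with a passing value. The most calls on named genes were lost without shNr4a3 replicate 1 (16 of 182) and without shNr4a3 replicate 2 (15 of 182); limma-voom lost 0 and DESeq2 4. Low counts limit Nr4a3, Myh6, Nppa, Tbx5, Rgs5 and Laptm5.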

Other observations

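The families and the genes of this part were chosen after the data were seen, as were the tests on mesothelial cells, S phase, small nucleolar RNA and library scaling. Among 232 families of genes with the same leading letters in their symbol and at least 8 tested members, 6 passed camera with the preset correlation and 0 with an estimated correlation. Each of the 6 shares genes with a fixed list tested above, so it is not independent of that result. Collagen genes (Col) fell in 18 of 34 cases and rose in 4, with a median log2 fold change of -0.49 (adjusted p = 2.1e-04, camera). Of 14 Klf genes, zinc finger transcription factors, 8 fell and 2 rose (adjusted p = 0.034, camera). The complex I families rose: 12 of 15 Ndufa genes (median 0.51) and 10 of 12 Ndufb genes (median 0.55; adjusted p = 0.046 for each, camera). The families Rpl (47 of 78 rose) and Rps (38 of 68), whose letters ribosomal protein genes carry, passed too. Grouping by leading letters can take in other genes that share them. Each of these families holds more members than the 54 tested of the fixed ribosomal protein list. With an estimated correlation the adjusted p was 0.98 for each of the 6. These directions held under all 4 scalings. The long noncoding RNA Neat1, a scaffold of nuclear paraspeckles, fell by 2.64 on the log2 scale (SE 0.06; adjusted p = 3.59e-25, edgeR), from 16328 and 18180 counts to 3103 and 2852.

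The fall of epicardial and mesothelial markers has the lowest p of the 29 lists in camera, with adjusted p = 0.23 with an estimated correlation. The list median stayed at or below -2.79 under 4 scalings. These scalings moved the median of all genes by at most 0.113, so that outcome was given in advance. It shows only that the choice among them is too small to account for the fall. Fewer mesothelial cells in the shNr4a3 libraries may account for it, but markers of that type alone would fall by 1 factor, and the members' log2 fold changes spanned 5.29, with Efemp1 lowest and Aldh1a2 highest at 0.29. This stays open, because fibroblasts can express some members and the design ties cell makeup to the hairpin. An effect of Nr4a3 loss on these genes within fibroblasts, and an effect of the hairpin on other transcripts, are untested: the labels name 1 hairpin against Nr4a3 and its sequence was not used here.

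Histone genes rose while mitosis genes fell, with adjusted p = 0.23 with an estimated correlation for each list (camera). A larger share of cells in S phase would raise DNA replication genes. Among the called members 17 fell and 4 rose (exact two-sided sign test p = 0.0072, over genes that are not independent). This argues against it for the called members only, and the count was known when the test was chosen. Of 47 tested members 26 did not pass, and the list passed fry as lower (adjusted p = 0.013) but not camera (adjusted p = 0.45). Reads moving between near-identical histone copies is argued against by the sum over the list, which rose by 1.29 on the log2 scale (SE 0.005). It went from 233 and 235 to 574 and 574 normalised CPM, and over all 39 listed core and linker histone genes the sum rose by 1.45. Most of the list sum comes from H1f2 (mean 134 to 270.9 normalised CPM) and H2bc4 (66.41 to 193.1), so it mainly describes those genes and less the copies with few counts. Better recovery of RNA without a poly(A) tail may contribute, as most histone transcripts lack one: 7 small nucleolar RNA genes pooled had a log2 ratio of 0.68 (95% exact counting interval 0.42 to 0.95). It stays open, because that rests on 508 reads, which can come from host introns, and a knockdown effect on histone transcripts is untested.

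Most oxidative phosphorylation and ribosomal protein genes rose by small amounts, but neither list passed fry (adjusted p = 0.076 and 0.10) or camera with an estimated correlation (adjusted p = 0.54 for each). Gene length and expression level are argued against: each list median lay above all 10000 random lists matched on both (percentile 100 for each; the highest 2.5% of random lists began at 0.15 and 0.09). Library scaling stays open: the lowest medians over 4 scalings were 0.41 and 0.32, but no scaling run lowered them by as much as 0.02, so it was not put to a test. The estimated correlations within these lists were 0.54 and 0.55, which are imprecise with 2 libraries per group. If the genes of a list move together to that degree, the random lists, which lack that, overstate how far the lists stand apart. A response of these genes to Nr4a3 knockdown is untested.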
